A study of Mus musculus with 2 samples.

How the data were processed

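H3K27ac ChIP-seq of E13.5 mouse midbrain was analysed from 4 deposited peak lists on mm10, 1 for each of 2 biological replicates, 1 from the pooled reads of both and 1 of replicated peaks. Per the text records deposited beside the lists, each replicate's list was derived from that replicate's alignments, the pooled list from both, and the replicated list from the other lists together. The aligner, the peak caller, their versions and their thresholds are not given in the sources used here. The lists' lowest −log10 p values lay between 2 and 2.05, and 22.0% of the peaks of each replicate's list had a −log10 q below 2, against 1.05% of the replicated list, so the replicates' lists are permissive.

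The lists are in narrowPeak format, per the deposited text records. Their ratio column is the authors' fold enrichment of a peak over the control, on a linear scale. The −log10 p and −log10 q columns hold the authors' significance of each peak. The deposited score column is a display value that was not used, and the summit offset was not used. No signal track was analysed here, so differences in signal between the replicates were not tested. A peak's fold is the authors' value for that peak and carries no error of its own.

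The replicates are numbered in the labels as biological replicates of separate tissue samples, and no label gives a batch. All statistics over peaks or genes describe these 2 libraries. Peaks and genes are not replicates, so p-values say how a set of peaks or genes lies against random positions or other genes, not how a further embryo pool would vary. The read depth is unknown. Exact binomial (Clopper-Pearson) 95% intervals are given for shares and cover counting error only.

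Gene models came from GENCODE M21 on GRCm38 patch 6, the assembly of mm10, and every peak on chromosomes 1 to 19 and X lay inside the chromosome lengths. Coordinates are 1-based. For 21728 protein-coding gene symbols on these chromosomes every annotated TSS was used. A gene had a promoter peak when a replicated peak overlapped the window of 1000 bp either side of any TSS, so 1 peak can count for neighbouring genes, and 2826 genes have no TSS farther than 5 kb from the TSS of another gene. Distal peaks lay more than 1 kb from every protein-coding TSS and were assigned to the nearest of these within 100 kb. Assignment by distance does not show which gene a site regulates. The promoter CpG ratio is observed over expected CpG within 500 bp of the TSS, with 1 value per gene.

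Overlap between replicates required 50% of either peak. Overlap and closeness to a TSS were set against 1000 random circular shifts within chromosomes (one-sided permutation test). Gene lists with promoter peaks were tested with Fisher's exact test, two-sided, against all other protein-coding genes, and gene lists with distal peaks by a two-sided permutation test against 10000 random lists matched on the tenth of territory length. Words in distal peaks were tested by the exact McNemar test, two-sided, on pairs of a peak and a window of equal length free of peaks. Each family was adjusted by Benjamini-Hochberg over its 23 lists or 10 words, at a level of 0.05. Large domains were those beyond the point of slope 1 on the scaled curve of ranked signal, and have no test.

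The gene lists, the families and the microRNA genes were written from general knowledge, not taken from a database. The 23 gene lists, the words, the tests and the main settings were chosen before the data were examined, as were most alternatives, namely TSS windows of 500 and 2500 bp, −log10 q of at least 2, 5 or 20, the pooled list, each replicate's own list in turn, gaps of 5 kb, assignment up to 500 kb, backgrounds of matched CpG ratio, and control windows 50 kb away, of matched GC content or of the central 500 bp. TSSs of the basic annotation, and TSSs apart from other genes by 5 kb, were added after the data had been seen. The text names the genes of the 10 domains of highest signal, per list the 3 members with the highest promoter fold and up to 3 without a promoter peak in alphabetical order, the 5 replicated peaks of highest fold, per replicate the 3 peaks of highest fold not overlapped in the other, and the 5 genes with most distal peaks. All other genes that the text names were chosen after their values were seen. Slc18a3 was a member of the glutamatergic list from the start, and only its mention in the text was chosen after its value was seen. Of the erythroid list Ahsp had no matching symbol.

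The procedures were tested on simulated data. With 40.0% of peaks planted as shared among 98807, 40.8% were found shared. In 200 simulations over 21728 genes, 98.6% of lists planted at 95% were called and 1.08% of unchanged lists. With backgrounds matched within random groups of genes the shares were 97.7% and 0.846%. No CpG ratio entered these groups, so the rates under matching on CpG ratio were not simulated. Lists planted with 3 times the distal peaks plus 3 further peaks per gene were called in 92.0% of cases over 50 simulations, and unchanged lists in 1.23%. This does not give the rate for a rise of 3 times alone. A word planted in 5% of 5000 sequences was called in 100% of 20 simulations, and unplanted words in 1.11% of cases. An earlier version of this last test, a single simulation with more sequences, had called an unplanted word, and the number of simulations was then raised to estimate the rate. Chromosome Y and scaffolds were left out of the comparisons. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.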

Results

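H3K27ac, the acetylation of lysine 27 of histone H3 that marks active promoters and enhancers, was mapped by ChIP-seq, in which DNA bound by an antibody against the mark is sequenced. The tissue was midbrain dissected from mouse embryos of the B6NCrl strain at embryonic day 13.5 (E13.5), with males and females pooled. At this stage the midbrain holds dividing neural progenitors together with young neurons. The labels give 1 group with 2 biological replicates, so no condition was compared with another, and the comparisons were between the replicates' peak lists, between gene lists, between chromosomes and between peaks and control sequence. Replicate 1 had 98828 peaks covering 50.6 Mb and replicate 2 had 107238 peaks covering 52.1 Mb. The list from both replicates' pooled reads had 123383 peaks over 69.9 Mb, and the list of replicated peaks, on which most results rest, had 59109 peaks over 54.2 Mb, of which 59095 lay on chromosomes 1 to 19 and X and covered 2.06% of them. The number of reads behind each list is not given in the sources used here. Fold values are the authors' enrichment over control for each peak. They served to describe, rank and filter peaks within a list, apart from a correlation between the replicates' lists and a comparison of X-linked with autosomal promoters.

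The first comparison asked how far the midbrain peaks of one embryo pool were found again in the other. Of replicate 1's peaks, 53.5% (52856 of 98807, exact 95% interval 53.2 to 53.8) were overlapped in replicate 2 over at least 50% of either peak, and of replicate 2's peaks 49.7% (53297 of 107225, 49.4 to 50.01) were overlapped in replicate 1. Chance gave 2.96% and 2.76% after the other list had been shifted around each chromosome, with highest values of 4.13% and 3.92% over 1000 shifts (permutation p = 0.001, one-sided, the smallest these shifts can give). Peaks at the promoters of Sp3 and Kmt5b, a transcription factor and a histone methyltransferase, led the replicated list, and strong peaks of this kind were shared almost without exception. Of 10 equal parts of each list by p, the part with the lowest p had 99.99% of replicate 1's peaks and 99.98% of replicate 2's overlapped, against 23.9% and 21.5% in the part with the highest p. Across 68385 pairs of peaks that overlapped by at least 1 bp, a looser rule than above, the folds of the replicates had a Spearman correlation of 0.567. This is a correlation across peaks, which are not independent replicates.

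**Figure D1:**
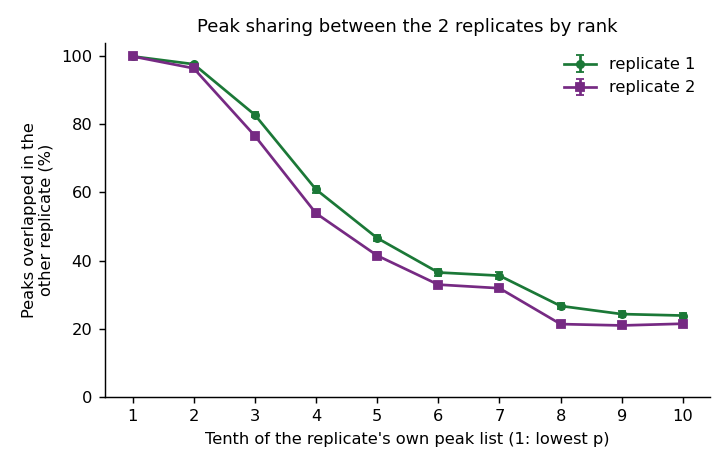
Share of each replicate's H3K27ac peaks (vertical axis, percent) overlapped in the other replicate over at least 50% of either peak, by 10 equal parts of the replicate's own list ordered by p (horizontal axis, 1 has the lowest p), with exact 95% intervals. The share went from 99.99% to 23.9% in replicate 1 and from 99.98% to 21.5% in replicate 2.

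Every replicated peak on chromosomes 1 to 19 and X had the same ends and the same fold as a peak of the pooled list. In the replicates' own lists 91.1% of the replicated peaks were overlapped in replicate 1, 92.4% in replicate 2 and 84.0% (49623) in both, so the replicated list also held peaks that were listed in only one replicate. The share of shared peaks depended on what counted as overlap and on the p and q values required, from 36.7% of replicate 1's and 33.8% of replicate 2's peaks when 50% of both peaks had to overlap to 82.7% and 83.4% among the 20000 peaks with the lowest p in each list.

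Midbrain H3K27ac gathered at promoters. Of the replicated peaks, 27.3% (16147 of 59095, exact 95% interval 26.96 to 27.7) lay within 1 kb of the transcription start site (TSS) of a protein-coding gene, against a mean of 5.40% and a highest value of 6.84% after random shifts (permutation p = 0.001, one-sided, the smallest these shifts can give). Promoter peaks were the strongest and widest, with a median fold of 8.26 and a median width of 888 bp, against 3.84 and 551 bp in introns and 4.01 and 569 bp between genes. By its centre, 25.5% of peaks fell within 1 kb of a TSS, which is 3.70% of the genome, 40.9% in introns (33.7% of the genome), 3.22% in exons (2.65%) and 30.4% between genes (60.0%). Among replicated peaks with a −log10 q of at least 20 the share near a TSS was 59.6%, and among all pooled peaks it was 18.3%.

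The 5 replicated peaks of highest fold were, on mm10, the promoter of Sp3 on chromosome 2 at 72978471 to 72981774 (fold 77.1), the promoter of Kmt5b on chromosome 19 at 3766676 to 3769391 (73.8), an intronic peak centred 1.32 kb from a TSS of Arrdc3 on chromosome 13 at 80882312 to 80887233 (73.6), the promoter of Zfp532, a zinc finger gene, on chromosome 18 at 65576793 to 65585764 (72.0) and the promoter of Klf7, a Krüppel-like factor gene, on chromosome 1 at 64117718 to 64123338 (70.1).

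At the level of genes, 11803 of 21728 protein-coding genes, 54.3% (exact 95% interval 53.7 to 55.0), carried a replicated peak within 1 kb of at least one TSS. The count was 9119 with only peaks of −log10 q of at least 20, 12803 with the pooled list, and 12352 and 12262 with replicate 2's and replicate 1's own lists, which share 11688 and 11667 genes with the main count.

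Every gene on the neural progenitor and pan-neuronal lists had a promoter peak in the replicated list. All 24 progenitor genes had a promoter peak (Fisher's exact test against all other genes, adjusted p = 3.62e-06), with the highest folds at Msi1, which encodes an RNA-binding protein of neural stem cells (59.3), the Notch ligand gene Dll1 (40.03) and Id4, an inhibitor of bHLH factors (37.9). All 22 pan-neuronal genes had one too (exact adjusted p = 1.08e-05), led by the genes of the microtubule-associated protein Map2 (39.1), the neuronal transcription factor Myt1l (38.9) and the microtubule regulator Stmn1 (37.9). These folds come from the pooled reads. The replicates' own lists gave 57.3 and 42.3 for Msi1, 33.0 and 31.1 for Dll1, 30.7 and 28.8 for Map2, and 23.3 and 36.0 for Stmn1. Progenitor genes were marked in 23 of 24 cases with a window of 500 bp and at a −log10 q of at least 5. At a −log10 q of at least 20 they were marked in 22 of 24. The list still passed in these settings, and pan-neuronal genes stayed at 22 of 22. The 25 cytosolic ribosome genes, active in every cell type, were likewise all marked (exact adjusted p = 2.52e-06), with Rps14 (32.7), Rpl3 (28.5) and Rpl32 (26.5) highest.

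Both large neurotransmitter classes of the midbrain were marked more often than other genes. Of the GABAergic genes, 18 of 19 had a promoter peak (Fisher's exact test, adjusted p = 0.000514), among them Gad2, which makes GABA (28.4), and the transcription factor genes Lhx5 (24.9) and Ascl1 (24.3). The exception was Helt, a determinant of midbrain GABAergic neurons, which was listed only in replicate 2 (3.15). Of the 19 genes, 5 also belong to another list: Ascl1 to the progenitor list, Tal1 to the erythroid list, and Dlx1, Dlx2 and Six3 to the forebrain and eye list. Of the glutamatergic and motor genes, 16 of 20 were marked (exact adjusted p = 0.0305), led by Nhlh2 (34.2), Ebf3 (32.0) and the vesicular glutamate transporter gene Slc17a6 (25.9). The 4 without a replicated promoter peak were Phox2a and Phox2b, which specify oculomotor and other brainstem neurons, and the cholinergic genes Chat and Slc18a3. Phox2b was listed in replicate 2 (2.80) and Phox2a and Chat in neither. The glutamatergic call ended with a window of 2500 bp, at a −log10 q of at least 20, with the pooled list and against CpG-matched genes (exact or permutation adjusted p = 0.0515, 0.0565, 0.0784 and 0.195), and the GABAergic call against CpG-matched genes (permutation adjusted p = 0.0514). Genes of mature synapses were also marked more often, 17 of 20 (exact adjusted p = 0.00985), with Shank2 (33.9), Homer1 (33.1) and Dlg4 (27.1) highest and Calb1, Pvalb and Slc17a7 without a peak, but not at a −log10 q of at least 20 (55.0%, exact adjusted p = 0.302). Target genes of the Wnt, Shh, Notch, FGF and BMP pathways were marked in 17 of 20 cases (exact adjusted p = 0.00985), with Axin2, a Wnt target (53.7), Smad7, a BMP target (52.9), and the Shh receptor gene Ptch1 (40.1) in front, and Etv4, Gli1 and Hhip without a replicated peak. That call ended at a −log10 q of at least 5 and of at least 20 (exact adjusted p = 0.0852 and 0.0565) and against CpG-matched genes (permutation adjusted p = 1).

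The lists of regional identity gave a mixed picture. Midbrain and isthmus patterning genes had a promoter peak in 14 of 20 cases (70.0%, exact 95% interval 45.7 to 88.1), against 54.3% of other genes. This difference did not pass (Fisher's exact test, adjusted p = 0.205). Among the marked genes were the homeobox genes Meis1 (29.1), En2 (21.9), En1 (20.4) and Otx2 (14.98). Fgf8 and Fgf17, whose products come from the isthmic organizer, had none in either replicate, and Dmbx1 was listed in both replicates (3.22 and 4.58) but not among the replicated peaks. With replicate 1's own list the count was 17 of 20 and passed the test (exact adjusted p = 0.0164), as did 18 of 20 with the pooled list (0.0081). With replicate 2's own list it was 16 of 20 and did not pass (exact adjusted p = 0.0534). Floor plate and dopaminergic genes were marked in 11 of 20 cases (exact adjusted p = 1). En1, which is also in the midbrain list, Neurog2 (15.1) and Shh (9.90) had the highest folds, Aldh1a1 and Drd2 had no peak in either replicate, and Corin was listed only in replicate 1 (3.64). Otx2 was named after its value was seen. Forebrain and eye genes were marked in 13 of 23 cases (exact adjusted p = 1). These included Emx2 (17.2), Six3 (13.2) and Sp9 (9.18), and Arx, Emx1 and Eomes had no replicated peak. Cell cycle genes were marked in 15 of 20 cases (exact adjusted p = 0.089, and 18 of 20 with 0.00421 in replicate 1's own list). Highest were Mcm7 (12.4, in a peak that also reaches the TSS of Ap4m1), Ccna2 (11.3) and E2f1 (10.6).

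Hox genes, whose expression marks the hindbrain and spinal cord, were almost free of the mark. None of the 24 posterior Hox genes had a replicated promoter peak (exact 95% interval 0 to 14.3%, Fisher's exact test, adjusted p = 7.71e-08), and 1, Hoxb9, named after its value was seen, had a peak in replicate 2's own list. Of the anterior Hox and hindbrain genes only Mafb (17.1) and Gbx2 (6.01), neither of them a Hox gene, had one among 20 (exact adjusted p = 0.000145). Atoh1 and Egr2, which act in the hindbrain, had none in either replicate.

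Markers of glia and of the vascular, meningeal and immune cells of the brain were marked less often than other genes in 3 of 4 lists. Endothelial genes were marked in 8 of 21 cases, 38.1% against 54.3% of other genes, which did not pass (Fisher's exact test, adjusted p = 0.205). The glucose transporter gene Slc2a1 (18.5) stood far above Mfsd2a (4.89) and Fli1 (4.84), and Cdh5, Cldn5 and Emcn had no replicated peak. Pericyte and meninges genes had a peak in 5 of 20 cases (exact adjusted p = 0.0169), with Vtn (22.4, in a peak that also reaches the TSS of Sarm1), Notch3 (12.4) and Foxd1 (5.17) highest. Microglia and macrophage genes had one in 4 of 19 (exact adjusted p = 0.00873), at low folds of 6.15 for C1qb, 4.28 for Hexb and 4.17 for Cd68. Glial genes had one in 5 of 19 (exact adjusted p = 0.0261), with the glutamate transporter gene Slc1a2 (24.5) far above the myelin gene Mbp (4.28) and Sox10 (3.67). In replicate 2's own list the glial count was 9 of 19 and the pericyte count 7 of 20, and neither passed (exact adjusted p = 0.529 and 0.0829). Glial and microglial genes did not pass against CpG-matched genes (permutation adjusted p = 0.406 and 0.89). With TSSs apart from other genes, glial, microglial and pericyte genes did not pass (exact adjusted p = 0.125, 0.0536 and 0.0534). Endothelial genes passed below at a −log10 q of at least 5 and 20 (exact adjusted p = 0.0381 and 0.000663). They lay above other genes with the pooled list, without passing (0.829).

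Lists from other tissues were also marked less often than other genes. Of 18 erythroid genes 1 had a peak (Fisher's exact test, adjusted p = 5.48e-05), and this was Tal1 (18.3), which also belongs to the GABAergic list, while Gata1, Alas2 and Epor had none in either replicate. Hepatocyte genes had 2 of 19 (exact adjusted p = 0.000229), Apoh, in a peak that reaches the TSS of Prkca (13.7), and Afp (4.84). The 2 of 19 epithelial genes (exact adjusted p = 0.000229) were the keratin genes Krt10 (25.4) and Krt1 (8.74). The peaks of Afp, Krt10 and Krt1 lie at annotated TSSs toward the downstream end of each gene, not at the gene's start. Muscle and heart genes had 5 of 21 (exact adjusted p = 0.0108), with Myh7 (20.5) highest and with Tnnc1 (14.9) and Mylpf (12.52) in peaks that also reach the TSSs of Nisch and Tbc1d10b. The muscle call ended with a window of 2500 bp and at a −log10 q of at least 20 (exact adjusted p = 0.0565 each). Against CpG-matched genes erythroid, hepatocyte and muscle genes did not pass (permutation adjusted p = 0.195, 0.377 and 0.564). The only pluripotency and germline gene of 20 with a peak, Gdf9 (6.29), shares it with Uqcrq (exact adjusted p = 1.47e-05 for the list). With only the TSSs of the basic annotation, hepatocyte genes had 0 of 19, epithelial genes 1 of 19 and pluripotency and germline genes 0 of 20. Olfactory receptor genes, which are expressed in the nose, were the largest list, and only Olfr94 (5.99) and Olfr452 (4.84) of 1134 had a peak, 0.176% against 57.3% of other genes.

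**Figure D2:**
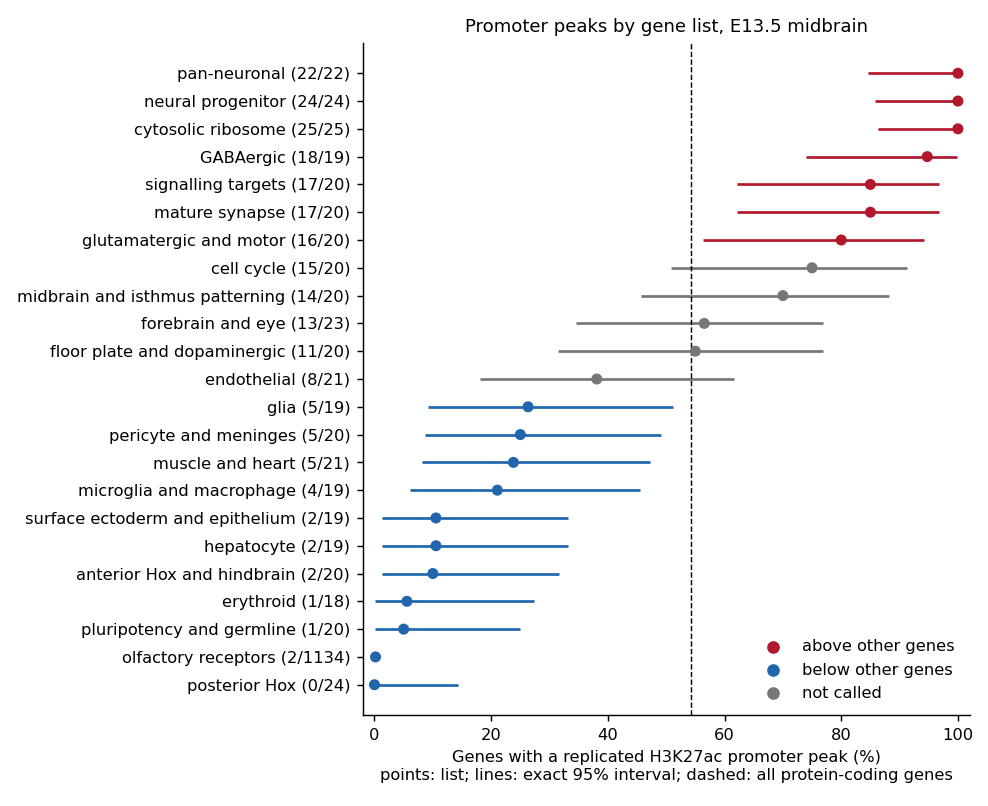
Percent of the genes of each list with a replicated H3K27ac peak within 1 kb of a TSS (horizontal axis), with exact 95% intervals, for 23 lists (vertical axis, genes with a peak over genes in the list). The dashed line is the 54.3% of all protein-coding genes, red lists passed Fisher's exact test above other genes, blue lists below and grey lists did not pass.

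In all, 7 lists lay above other genes and 11 below. Against genes of similar promoter CpG content, progenitor, pan-neuronal, mature synapse and ribosome genes stayed above (permutation adjusted p = 0.000767, 0.000767, 0.00526 and 0.00971), and GABAergic (0.0514), glutamatergic (0.195) and signalling genes (1) did not pass. Of those below, both Hox lists, pluripotency, olfactory receptor (0.000767 each, permutation adjusted p), epithelial (0.00575) and pericyte genes (0.0386) stayed, and glial (0.406), microglial (0.89), erythroid (0.195), hepatocyte (0.377) and muscle genes (0.564) did not.

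Away from promoters, 4 of the 23 lists had more acetylated sites around their genes than random lists, with the highest mean for pan-neuronal genes. Of the replicated peaks, 42948 (72.7%) lay more than 1 kb from every protein-coding TSS, and 33454 of these had a nearest TSS within 100 kb. Pan-neuronal genes had a mean of 14.7 such distal peaks, against 3.98 in random lists with nearest-TSS territories of similar length (permutation adjusted p = 0.00307), glutamatergic and motor genes 10.1 against 2.44 (0.0023), GABAergic genes 8.05 against 2.23 (0.00805) and progenitor genes 8.38 against 3.16 (0.0322). Rbfox3, the gene of the neuronal marker NeuN, named after its value was seen, had 59 distal peaks, Ebf3 53 and Myt1l 52. Ebf3, Ebf1 (43) and Ebf2 (23) held a large part of the 201 distal peaks of the glutamatergic and motor list. Rbfox3, Myt1l, Ncam1 (41) and Nrxn1 (29) likewise held a large part of the 323 distal peaks of the pan-neuronal list. Neither list was tested without these genes. The medians were 9 for pan-neuronal, 7 for GABAergic, 6 for progenitor and 5 for glutamatergic and motor genes. Midbrain and isthmus patterning genes had 7.90 against 3.31, which did not pass at the main setting (permutation adjusted p = 0.0782). They passed at a −log10 q of at least 20 (permutation adjusted p = 0.0253), by distal bases (0.0353) and in replicate 2's and replicate 1's own lists (0.0204 and 0.0245). They did not pass at a −log10 q of at least 5 (0.0652), with the pooled list (0.0615), up to 500 kb (0.126) or beyond 2500 bp from a TSS (0.0935). Mature synapse genes, frequent among genes with a promoter peak, had 2.55 against 2.93 (permutation adjusted p = 0.912). Olfactory receptor genes lay below random lists at 0.0221 against 0.408 (permutation adjusted p = 0.0023), and the posterior Hox genes had no distal peak against 0.294 (permutation adjusted p = 0.125, and 0.012 and 0.0245 in the replicates' own lists and 0.0248 in the pooled list). Ribosome genes had 1.20 against 0.441 (permutation adjusted p = 0.102) and passed only with the pooled list (0.0406). The smallest permutation p that 10000 random lists can give is 0.0002 before adjustment.

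**Figure D3:**
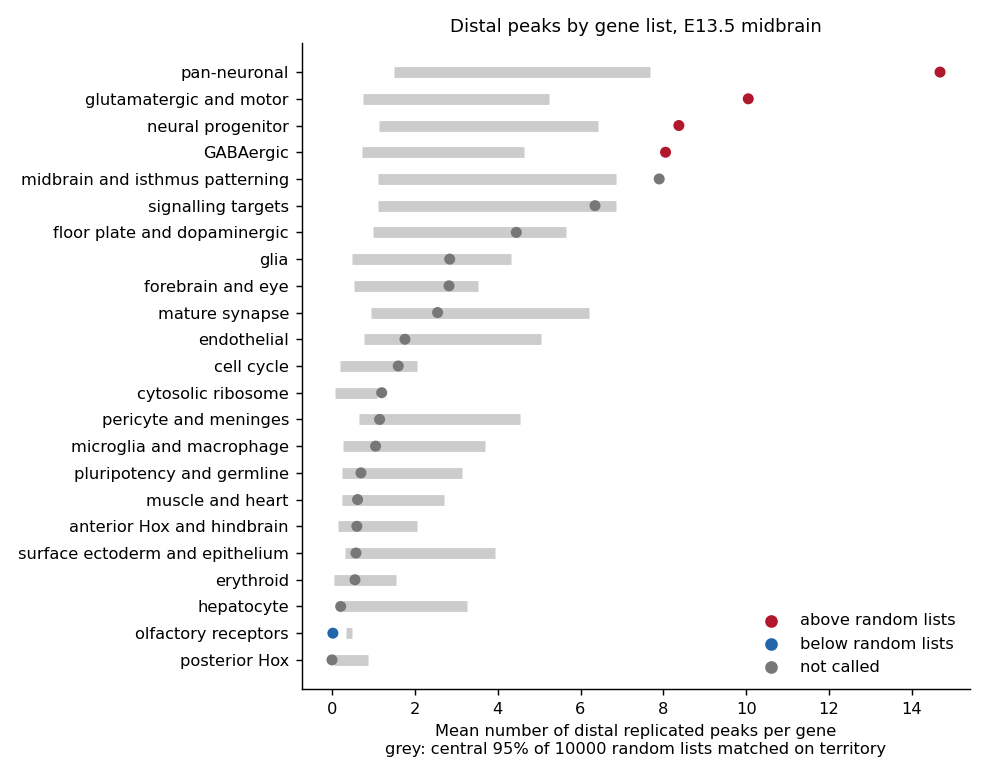
Mean number of distal replicated peaks per gene (horizontal axis) for 23 gene lists (vertical axis, points), with the central 95% of 10000 random lists matched on the tenth of territory length as grey bars. Pan-neuronal genes lie farthest to the right at 14.7, and red and blue points passed the permutation test above and below random lists.

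The genes with most distal peaks were Msi2, the relative of Msi1 (121), Zmiz1, a transcriptional coregulator gene (105), Rere (85), Gse1 (74) and Frmd4a (73). Their territories were long, from 290 kb for Msi2 to 691 kb for Frmd4a, and each also had a promoter peak, with folds of 18.9, 47.7, 27.2, 56.6 and 44.6 in the same order. The mean over all genes was 1.54 distal peaks, and 7345 genes had at least 1. The call for GABAergic genes ended when peaks up to 500 kb were assigned (permutation adjusted p = 0.0534), and that for progenitor genes with the pooled list (0.0615).

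Genes on the X chromosome, of which female cells keep 1 copy active and male cells have 1 copy, carried promoter peaks less often than autosomal genes. The share was 38.1% (361 of 948, exact 95% interval 35.0 to 41.3) on X and 55.1% (11442 of 20780, 54.4 to 55.7) on the autosomes, an odds ratio of 0.502 (0.438 to 0.575, Fisher's exact test, two-sided, p = 1.17e-24). Where X-linked genes had a peak, its median fold was 10.01 against 12.2 for autosomal genes (permutation p = 0.0016, two-sided, over genes, which are not independent replicates). X had 5.52 replicated peaks per Mb, and the autosomes ranged from 17.7 to 36.3. Neural genes on X were nonetheless marked: Dcx, a microtubule protein gene of migrating neurons, had a fold of 18.4, the patterning gene Pou3f4 17.4, Sox3 7.84, the adhesion gene L1cam 7.34 and the synapsin gene Syn1 5.68, while Arx, Plp1, Gata1 and Alas2 had no promoter peak. These are all X-linked genes of the lists apart from olfactory receptors, named after their values were seen.

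Joined across gaps of up to 12500 bp (median 1054 bp), the replicated peaks formed 24534 domains, and 763 of these stood above the bend of the ranked curve of signal (peak width times fold) and held 35.5% of it. The large domains had a median length of 33.2 kb and 9 peaks. The domain of highest signal lay on chromosome 2 at 30591159 to 30808710, held 59 peaks over 218 kb and contains the TSSs of Cstad, 1700001O22Rik and Ntmt1. The next were on chromosome 8 at 120250521 to 120590072 with Gse1 and Gins2, and on chromosome 11 at 88233108 to 88730062 with Msi2 and Ccdc182, where 208 peaks spread over 497 kb. The domain ranked 4 by signal, on chromosome 13 at 83713742 to 83753513, holds no protein-coding TSS (the nearest belongs to Mef2c) but holds Mir9-2, a gene for the brain microRNA miR-9. Its 16 peaks covered 84.9% of its 39.8 kb, with a top fold of 65.9.

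**Figure D4:**
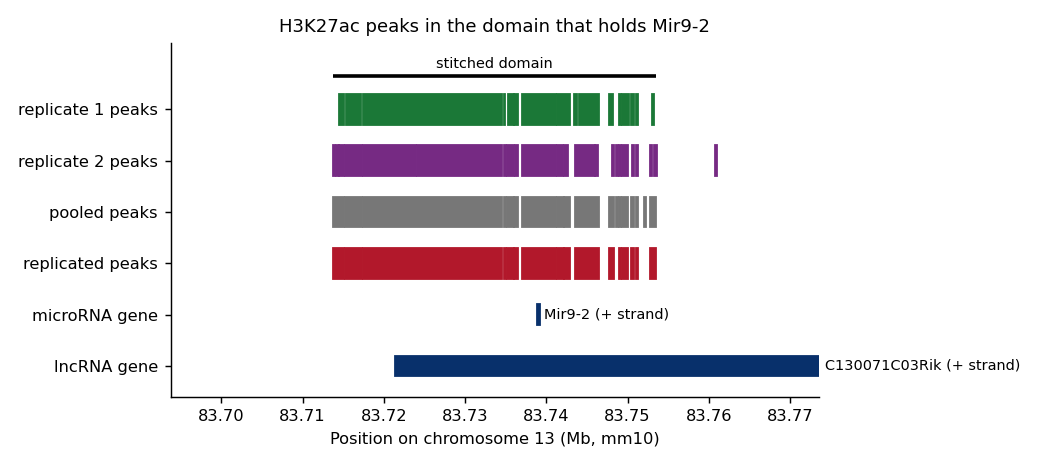
H3K27ac peaks of the replicates' own lists, the pooled list and the replicated list around Mir9-2 (horizontal axis, position on chromosome 13 in Mb, mm10), with the stitched domain as a black bar and the gene of the microRNA and of the long noncoding RNA C130071C03Rik, which runs past the right edge. The 16 replicated peaks fill 84.9% of the domain from 83713742 to 83753513.

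Further down the 10 domains of highest signal, chromosome 10 at 80136837 to 80270853 held 10 protein-coding TSSs, those of 1600002K03Rik, Atp5d, Cbarp, Cirbp, Dazap1, Efna2, Gamt, Midn, Mum1 and Ndufs7, with Midn (57.6) and the cold-inducible RNA-binding protein gene Cirbp (42.7) strongest. The others were Zmiz1 on chromosome 14 at 25445335 to 25645861, the tubulin genes Tuba1a and Tuba1b with Gm49450 on chromosome 15 at 98933335 to 98998270, an internal region of Zfhx3 on chromosome 8 at 108690608 to 108727594, a stretch on chromosome 12 at 117149271 to 117288659 that holds the microRNA gene Mir153 and is nearest to the TSS of Rapgef5, and Bahcc1 on chromosome 11 at 120207198 to 120317867. All 10 counted as large in both replicates' own lists and at a −log10 q of at least 20. Without peaks within 2500 bp of a TSS the Zfhx3 domain was no longer large, and the number of large domains was 416, as it was 459 at a −log10 q of at least 20.

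Peaks found in one replicate only were weak and mostly away from promoters. Replicate 1 had 39442 peaks (39.9%) without a 1 bp overlap in replicate 2, and replicate 2 had 47234 (44.1%) without one in replicate 1. Their median fold within their own lists was 3.20 and 3.15, against 4.31 and 4.29 for shared peaks, and 10.2% and 9.81% lay within 1 kb of a TSS, against 28.8% and 28.9% of shared peaks. The strongest in replicate 1 reached a fold of 7.73, 19.7 kb from a TSS of Fzd2 on chromosome 11 at 102623912 to 102624220, followed by peaks nearest to Msra (7.37) and Igsf3 (7.34). In replicate 2 they were an exonic peak nearest to Nr1i2 on chromosome 16 at 38307952 to 38308296 (8.68) and peaks nearest to Laptm5 and Dnah9 (8.30 each). Of the 39442 and 47234 peaks, 18.8% and 18.1% were nevertheless overlapped in the replicated list. With a −log10 q of at least 5 the numbers fell to 2577 and 2535, of which 55.2% and 60.4% were overlapped in it. When an overlap of 50% of either peak was required, 45951 and 53928 peaks were not shared. Their median folds were 3.22 and 3.15, and their highest folds 10.8 and 28.2.

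Distal peaks were compared with control windows of the same length 10 kb away for 10 short words bound by families of transcription factors. Distal peaks can still lie at TSSs of genes that do not code for protein. Of all replicated peaks, 18561 lay within 1 kb of a TSS of any gene, against 16147 for protein-coding genes. Words at such TSSs were not tested apart. The E-box CAGCTG, a site of proneural bHLH factors, differed most in percentage points, in 40.8% of 38725 distal peaks against 26.4% of their controls (odds ratio 2.16, exact 95% interval 2.08 to 2.23). The palindromic RFX site was rare but had the highest odds ratio, 6.07 (3.49 to 11.3, exact McNemar test, adjusted p = 3.17e-14), in 0.235% against 0.0387%. Above 1 were also TGCGCA (1.81), the ETS word CCGGAAG (1.64), the POU octamer ATGCAAAT (1.27), the other E-box CAGATG (1.16) and the SOX word ACAATGG (1.08), with exact adjusted p from 5.9e-61 to 0.00225. The GATA word AGATAA (0.812, exact adjusted p = 1.39e-34), the AP-1 word TGACTCA (0.905, 2.65e-05) and the homeodomain word TAATTA (0.960, 0.0418) were less frequent than in the controls.

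Peaks had a GC content of 49.0% against 44.5% in the controls. With 19700 pairs of GC content within 5 percentage points, TAATTA turned to an excess (odds ratio 1.48, 1.40 to 1.57, exact McNemar test, adjusted p = 1.15e-42), AGATAA no longer differed by the test (1.04, exact adjusted p = 0.118), and TGACTCA stayed below 1 (0.850, exact adjusted p = 3.45e-07). The call for TAATTA also ended with controls 50 kb away (0.9625, exact adjusted p = 0.0524) and in the central 500 bp, where the odds ratio was 1.04 (exact adjusted p = 0.0544). Most words above 1 also moved toward 1 with matched GC. CAGCTG fell to 1.68 (41.2% against 31.2%), RFX to 4.73, TGCGCA to 1.52, the ETS word to 1.25 and CAGATG to 1.08. The POU and SOX words rose to 1.55 and 1.09. All of these still passed (exact adjusted p of at most 0.00807).

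**Figure D5:**
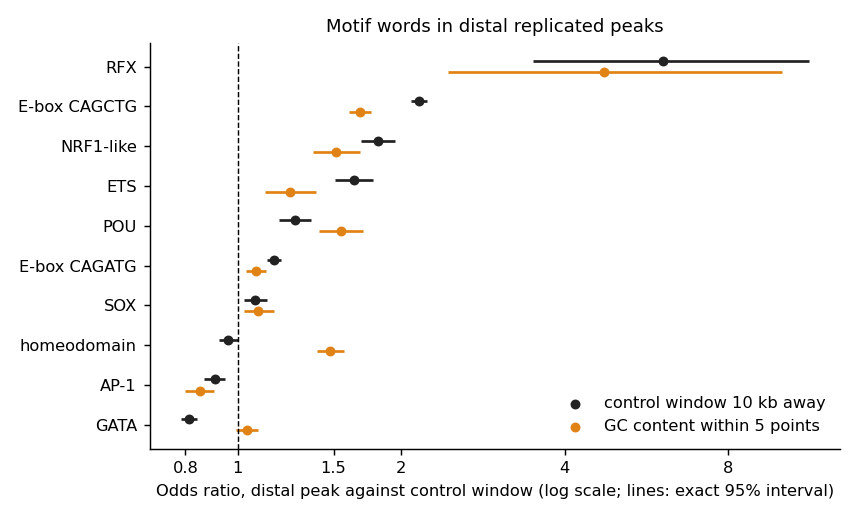
Odds ratio of finding each word in a distal peak against its control window (horizontal axis, log scale, with exact 95% intervals) for 10 transcription factor words (vertical axis). Black points use windows 10 kb away, orange points only pairs of similar GC content, and the homeodomain word moves from 0.960 to 1.48 between them.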

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

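Control windows of matched GC content were among the alternatives named above. Their use to weigh GC content as an explanation for the words in distal peaks was chosen only after the result was seen. The other tests in this part were chosen before.

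Peaks were also listed outside the chromosomes used in the comparisons. The replicated list held 5 peaks on chromosome Y, the strongest of these at 1244969 to 1245723 with a fold of 7.18. It also held 9 peaks on unplaced or unlocalised scaffolds, with a highest fold of 49.7. Both numbers exceeded the 3 set as the limit for a count of 0. Called peaks are not counts around 0, so this limit cannot decide whether there is signal. The pools hold males, so peaks on Y are no surprise in themselves. Replicate 1's own list had 9 peaks on Y and replicate 2's 3. No list had a peak on the mitochondrial genome.

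The lower share of X-linked genes with a promoter peak is the first pattern weighed. Among genes with a promoter CpG ratio of at least 0.6 the odds ratio was 0.651 (0.472 to 0.914, Fisher's exact test, p = 0.0119). Without gene families of 5 or more on a chromosome it was 0.562 (exact p = 8.83e-11). These values argue against CpG make-up, as measured by 1 ratio per gene, and against reads shared between copies as the whole cause. The CpG ratio may still account for part of the deficit, since X-linked promoters have a lower median ratio (0.386 against 0.568) and the odds ratio rose from 0.502. A lower read depth of X stays open: the odds ratio at a fold of at least 10 was 0.490 (exact p = 1.68e-19), but weaker signal on X, where the median fold was 10.01 against 12.2, would itself leave fewer peaks above that fold, so the deficit set as the sign against depth was wrongly chosen. A lower acetylation per cell of a chromosome with 1 active copy stays open too and was not tested, because the design does not separate males from females.

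The second pattern is the low frequency of the homeodomain and GATA words in distal peaks, although homeobox and GATA genes are marked in this tissue. GC content is a candidate explanation. With controls of matched GC the odds ratio of TAATTA rose from 0.960 to 1.48 (1.40 to 1.57) and that of AGATAA from 0.812 to 1.04, so for these AT-rich words the comparison with windows 10 kb away depends on the higher GC content of peaks. The low frequency of the AP-1 word did not go with GC content, since its odds ratio was 0.850 (0.799 to 0.904, exact McNemar test, p = 2.07e-07) with matched controls. No biological explanation was tested.

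The third pattern is the excess of promoter peaks in the lists called above other genes, most of which have a higher median promoter CpG ratio than autosomal genes (0.568), mature synapse genes (0.460) being the exception. Against genes of matched CpG ratio 4 lists were still called above, progenitor, pan-neuronal, mature synapse and ribosome genes. Each gene has 1 ratio while a peak counts at any of its TSSs, so the ratio need not describe the marked TSS. For these lists the test argues only against CpG make-up by this ratio as the whole explanation. For signalling genes CpG make-up may account for most of the excess (85.0% against 82.6% in matched genes, permutation adjusted p = 1). For GABAergic (94.7% against 73.5%, permutation adjusted p = 0.0514) and glutamatergic genes (80.0% against 63.8%, 0.195) the call ended while much of the excess stayed, so it stays open how far CpG make-up accounts for it. No biological explanation was tested, since there is 1 tissue and 1 stage.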

How the results depend on the processing

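The TSSs of the basic annotation and the TSSs apart from other genes were tried only after the data had been seen. Of 1779 recomputed values, 1647 kept their direction and side of the threshold or their size, 67 moved, 25 turned, 27 no longer passed a test and 13 newly passed one. Gene lists moved most, with 189 of 230 values the same, against 1080 of 1136 for named promoters, 164 of 184 for distal peaks of lists, 69 of 70 for the top domains and 46 of 50 for words. Except where the setting itself sets the number of peaks, the cause was not tested.

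Against genes of matched CpG ratio 10 lists were called, 4 above and 6 below, and at a −log10 q of at least 20 there were 4 above. The shares of genes with a peak are given here with permutation or exact adjusted p. With matched CpG ratio the share is the same and only the comparison moves: GABAergic 94.7% (0.0514), glutamatergic 80.0% (0.195), signalling 85.0% (1), glial 26.3% (0.406), microglial 21.1% (0.89), erythroid 5.56% (0.195), hepatocyte 10.5% (0.377) and muscle genes 23.8% (0.564) no longer passed, and midbrain 70.0% (0.931), floor plate 55.0% (0.564), forebrain 56.5% (0.585) and cell cycle genes 75.0% (0.558) lay below the matched background without passing. At a −log10 q of at least 20, floor plate genes were at 30.0% (0.383), glutamatergic 65.0% (0.0565), mature synapse 55.0% (0.302), forebrain 30.4% (0.325), muscle 19.1% (0.0565), cell cycle 40% (1) and signalling genes 65.0% (0.0565), and endothelial genes passed below at 4.76% (0.000663). At a −log10 q of at least 5, forebrain genes were at 52.2% (1) and signalling genes at 75.0% (0.0852), and endothelial genes passed at 28.6% (0.0381).

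With the pooled list midbrain genes passed at 90.0% (exact adjusted p = 0.0081), endothelial genes turned to 61.9% (0.829), and glutamatergic 80.0% (0.0784), glial 36.8% (0.0784) and pericyte genes 35.0% (0.0529) did not pass. With a window of 2500 bp, glutamatergic 80.0% (0.0515), glial 31.6% (0.0515) and muscle genes 33.3% (0.0565) did not pass in the exact test. Forebrain genes were at 52.2% with 500 bp and with the basic annotation (exact adjusted p = 1 each). With TSSs apart from other genes, glial 26.3% (0.125), microglial 18.8% (0.0536) and pericyte genes 21.1% (0.0534) did not pass in the exact test. With each replicate left out in turn, the shares lay between 80.0% and 85.0% for midbrain, 52.2% and 65.2% for forebrain, 31.6% and 47.4% for glial, 25% and 35.0% for pericyte and 80.0% and 90.0% for cell cycle genes.

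The ratio of distal peaks to random lists turned without passing a test for erythroid genes (0.701 at a −log10 q of at least 5, 0.578 pooled, 0.700 within 500 kb, 0.948 beyond 2500 bp, 0.822 by bases, and 0.583 to 0.859 with a replicate left out), for microglial genes (1.02 at a −log10 q of at least 20, 1.18 within 500 kb) and for cell cycle genes (0.697 at a −log10 q of at least 20). Large domains numbered 416 without peaks within 2500 bp of a TSS and 459 at a −log10 q of at least 20. Peaks of one replicate alone numbered 24784 and 30442 at a −log10 q of at least 2, and 2577 and 2535 at 5. The homeodomain word stood at 0.9625 without passing with controls 50 kb away and turned to 1.04 in the central 500 bp and 1.48 with matched GC, and the GATA word to 1.04 with matched GC. No read depth is known, so it is open whether a promoter without a peak lacks the mark or lies below detection.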

Other observations

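The gene families, the gene lists in large domains and the microRNA genes were tested only after the main results had been seen.

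Gene families grouped by symbol, some of whose Lhx, Sox and Zic members also belong to the lists, differed in how they were marked. Of 18 families, ephrins and Eph receptors, which guide axons, had a promoter peak in 20 of 22 genes (Fisher's exact test, adjusted p = 0.000936), which did not pass against CpG-matched genes (77.9%, permutation adjusted p = 0.232), and a mean of 9.09 distal peaks against 3.15 in random lists (permutation adjusted p = 0.0144), and Ephb2 alone had 68. All 4 Nfi genes, transcription factor genes of glial and neuronal maturation, were marked, Nfib most strongly (28.9), which did not pass the test (Fisher's exact test, adjusted p = 0.181), with 19 distal peaks on average against 3.92 (permutation adjusted p = 0.0422). Slit and Robo genes, another guidance system, had 15.4 against 4.45 (permutation adjusted p = 0.0436), with 41 at Slit1 and 37 at Robo1, and did not pass for promoters (5 of 7, exact adjusted p = 0.558). Of the Lhx genes 4 of 8 had a promoter peak (exact adjusted p = 1), Lhx5 (24.9), Lhx2 (24.8), Lhx9 (23.3) and Lhx1 (15.6), while Lhx3, Lhx4, Lhx6 and Lhx8 had none, and the mean was 6.25 distal peaks against 1.72 (permutation adjusted p = 0.0324). All 5 Zic genes were marked, Zic2 highest (33.2), which did not pass the test at this size (Fisher's exact test, adjusted p = 0.101), and of 19 Sox genes 15 were marked (exact adjusted p = 0.0608), Sox11 (60.1) and Sox4 (53.7) among them.

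The clustered protocadherins, adhesion genes of which each neuron expresses a few, were marked less often than other genes. A promoter peak was found at 1 of 13 Pcdha, 0 of 22 Pcdhb and 6 of 21 Pcdhg genes (Fisher's exact test, adjusted p = 0.0022, 9.67e-08 and 0.047), against 78.9%, 37.5% and 68.3% of genes of matched CpG ratio (permutation adjusted p = 0.00072 each). The 67 histone cluster genes stood at the other end with 58 marked (exact adjusted p = 8.22e-08), which was not more than CpG-matched genes (88.6%, permutation adjusted p = 0.826). Zinc finger genes were marked in 300 of 394 cases against 62.0% of CpG-matched genes (permutation adjusted p = 0.00072). Vomeronasal receptor genes (1 of 328), defensins (0 of 64) and cytochrome P450 genes (12 of 100) were marked rarely. Semaphorins were marked in 16 of 20 cases (exact adjusted p = 0.047), which did not pass against CpG-matched genes (65.5%, permutation adjusted p = 0.232). Fox genes, marked in 25 of 44 cases (exact adjusted p = 0.809), lay below CpG-matched genes (73.4%, permutation adjusted p = 0.0153) but had more distal peaks than random lists (4.61 against 2.26, permutation adjusted p = 0.0422). Irx (4 of 6) and potassium channel genes (44 of 93) passed neither test (exact adjusted p = 0.781 and 0.227 for promoters, permutation adjusted p = 0.883 and 0.946 for distal peaks).

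Of all protein-coding genes, 5.61% (1218 of 21728) had a TSS inside a large domain. Among progenitor genes it was 11 of 24 (Fisher's exact test, adjusted p = 2.4e-07), including Sox1, Sox2, Nes and Notch1, among GABAergic genes 9 of 19 (exact adjusted p = 2.25e-06), including Gad1, Gad2, Gata3 and Lhx1, among pan-neuronal genes 8 of 22 (8.64e-05, exact), and among glutamatergic and motor genes 7 of 20 (0.000266, exact). Midbrain and isthmus patterning genes, which did not pass by promoter peaks in the replicated list, were in large domains in 7 of 20 cases (exact adjusted p = 0.000266), namely Cnpy1, En1, En2, Meis2, Otx2, Pax3 and Pax7. Signalling targets had 6 of 20 (exact adjusted p = 0.00198) and mature synapse genes 1, Dlg4. No gene of the Hox, endothelial, pericyte, erythroid, hepatocyte, muscle, epithelial, pluripotency or olfactory receptor lists was in one. Of these, only olfactory receptor genes lay below other genes by the test (exact adjusted p = 2.48e-28). The others did not pass (exact adjusted p = 0.87 each). Large domains are built from the same replicated peaks, promoter peaks included, so these counts are not independent of those by promoter peaks. The tests set each list against all other genes, without matching on promoter peaks or CpG ratio.

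That Mir9-2 and Mir153 lie in 2 of the 10 domains of highest signal led to the hypothesis that microRNA genes known from brain lie in large domains more often than other microRNA genes. Of 24 such genes, listed from general knowledge and after these had been seen, 13 (54.2%, exact 95% interval 32.8 to 74.5) overlapped a large domain, against 118 of 2171 other microRNA genes (5.44%), an odds ratio of 20.6 (8.27 to 51.7, Fisher's exact test, p = 9.66e-11). The 13 genes lie in 12 domains, since Mir132 and Mir212 share one. All 3 miR-9 genes were in domains of high rank (4, 12 and 21), as were the 3 miR-124 genes (20, 26 and 49) and Mir125b-1 (44), whereas Mir137, Mir128-1, Mir218-1 and Mir218-2 were in no large domain. Mir9-2, Mir153, Mir9-3 and Mir124a-1 lie in the 20 domains of highest signal, which had been seen when the genes were listed. Without all microRNA genes in these domains, 9 of 20 brain genes and 109 of 2162 others overlapped a large domain, an odds ratio of 15.4 (5.50 to 41.7, Fisher's exact test, p = 2.97e-07). The choice of the remaining genes may still have been guided by those seen.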
